A study of Mus musculus with 24 samples.

How the data were processed

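The series compared mice carrying human PER1 with the variant S714G (called mutant here) with mice carrying human PER1 with S714 (called control). Per the labels, all mice were male, 2 months old and on a C57BL/6 background. They were kept on light-dark cycles for 10 days, and samples of liver and of white adipose tissue date from ZT1 and ZT13, hours counted from lights on. Tissues were frozen in liquid nitrogen and total RNA was extracted with Trizol. Tissue, genotype and time gave 8 groups of 3 arrays, 24 arrays in all. Each RNA was hybridised to a Cy3 Agilent mouse array with 62976 spots per array, and the 24 arrays lay on 3 slides of 8.

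Per the file headers, the deposited scanner files hold spot intensities, in arbitrary units, from Agilent Feature Extraction 10.7.3.1. Its processed signal is an intensity from which the authors' scanner software had subtracted background and spatial trend, without scaling between arrays. Per the file headers, the scanner also set other columns of 0 or 1 flags per spot for signal well above background, saturation and outlying pixels. The deposited table of processed values is on a log2 scale. Its column medians lay between -3.92 and -3.03. Every column equalled log2 of its own array's processed signal minus a single constant, to within 0.01 for at least 99.4% of probes, and had a 75th percentile of 0. Its scale and direction were therefore settled from the values, and no centring by probe was seen. How the constant was chosen is not stated. All values below were computed from the scanner intensities.

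Control spots and spots with outlier flags (0.238% to 0.685% of the non-control spots of an array) were left out. Spots of the same probe were averaged, which gave 55681 probes. The log2 processed signal of each array was set relative to its own 75th percentile. A probe entered the fit of a tissue where it was well above background on all 3 arrays of at least 1 group. Probes with no usable value in a group could not be fitted. Probes were named from RefSeq accessions (26762 probes), from a current symbol (3819), from a synonym (639) or kept the name in the files (24461). Each gene was represented by its brightest probe in the tissue. This left 25469 genes in liver, 27895 in adipose tissue and 29143 in the fit of both tissues. Probe positions are those of the array design on mouse build mm9. No genome annotation was used, so the exon or untranslated region under a probe is not given.

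Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 4 group means per tissue over 12 arrays, or 8 group means over 24 arrays for the comparison of tissues. Adjusted p is the Benjamini-Hochberg value over all genes tested, with 0.05 as threshold, and SE is the standard error from the fit. The contrasts were mutant minus control at each time and averaged over times, ZT13 minus ZT1 in each genotype, the difference of those changes, and the difference of the genotype effects between tissues. Where a gene was not well above background on any of the dimmer group's arrays, a fold bound is given. The bound sets the bright group's mean over all replicates against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Tables were handled with the R package data.table (version 1.17.8), Python 3.11.15 and pandas 2.3.3, and drawn with matplotlib 3.10.9.

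Gene lists were written from textbook knowledge. They numbered 37, with 592 of their 600 members on the array, and covered the clock, lipid, sterol, bile acid and glucose metabolism, xenobiotic metabolism, stress and hormone responses, ribosome biogenesis, oxidative phosphorylation, sex-biased liver genes, inflammation, proliferation and markers of 15 cell types. A list entered where at least 4 members passed the filter. The lists of epididymis and testis markers never did and gave no result. Shifts of a list against all other genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. A clock index was computed per array as the mean log2 signal of 8 daytime genes (Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per3, Ciart and Usp2) minus that of 5 late-night genes (Arntl, Clock, Npas2, Nfil3 and Cry1). Its differences were tested by exact two-sided permutation.

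Genes named in the text follow a rule. It takes all 23 core clock genes, then for each genotype contrast the 10 genes per direction with the largest difference among those with an adjusted p under 0.05, an ordinary symbol and no overlap between the 3 mutant and 3 control values. Where fewer than 5 per direction passed, genes of lowest p were added and are given as not past the threshold. For the other contrasts 5 per direction were taken. Overlap was checked only where a single group was set against another, and not for averages over times, interactions or differences between tissues. Up to 4 members of lowest p were added from each list that passed or had a member past the threshold. Some genes that the rule takes are not reported here. Chance gives no overlap in 10% of comparisons of 3 with 3. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

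On simulated data with the spread of these arrays, the fit was tested with 100 genes changed 2-fold and 100 changed 4-fold. At ZT13 in liver it recovered 49 and 93 of them, with 10 unchanged genes called. At ZT13 in adipose tissue it recovered 7 and 61, with 2 unchanged genes called. The simulated values were drawn independently for each gene and array and held no slide effect. These counts therefore do not measure false calls that slide could cause in the real arrays. Alternatives covered quantile normalization, normexp background correction with an offset of 50, the deposited log2 table, no filter and a strict filter on dim probes, all probes, a trend in the prior, other sets of arrays in the fit, a replicate block, slide as a fixed or a random block, arrays of a single slide, the code in the titles as a covariate, the index without each member, and each replicate left out. Those added after the data were seen left out the arrays of slide 1, left out genes over 8-fold higher in liver than in adipose tissue, or took the clock index within a slide. No array and no sample was left out of the results as reported.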

Results

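Gene expression was measured in liver and white adipose tissue of mice that carry human PER1 with the change S714G (mutant) or without it (control), at ZT1 and at ZT13. PER1 is a repressor protein of the circadian clock, and the design asks how the variant changes expression in a metabolic tissue at a given time of day. Each of the 8 groups had 3 arrays, and the number of arrays limits the precision. Between 45.5% (liver control ZT1 replicate 3) and 71.2% (adipose control ZT1 replicate 1) of the spots on an array were well above background. The 75th percentile of the signal ran from 405 (liver control ZT1 replicate 1) to 2015 (adipose control ZT13 replicate 2), and on slide 1 it did not exceed 1399. Slide 1 held the control ZT1 arrays of both tissues and adipose mutant ZT1 replicates 1 and 2. Slide 2 held adipose mutant ZT1 replicate 3, the liver mutant ZT1 arrays, the adipose control ZT13 arrays and liver control ZT13 replicate 1, and slide 3 held the rest. Both genotypes shared a slide in liver at ZT13 (slide 3, 2 control and 3 mutant arrays) and in adipose tissue at ZT1 (slide 1, 3 and 2 arrays), and in no other genotype comparison. In the comparisons of ZT13 with ZT1, no slide held both times of the same tissue and genotype.

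**Figure D1:**
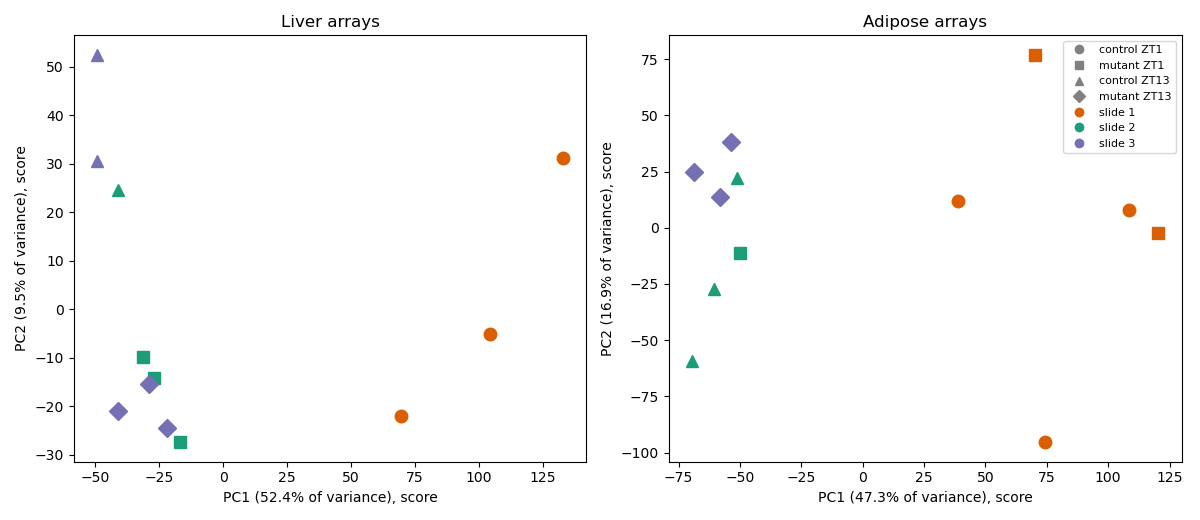
Principal components of the 12 liver and 12 adipose arrays, computed on log2 signal; each point is an array, the colour gives its slide and the shape its group, and the axes are component scores. In liver the first component holds 52.4% of the variance and in adipose tissue 47.3%, and along it the arrays of slide 1 lie apart from the others.

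In liver at ZT13, the late-night genes of the clock index were higher in mutants and most of its daytime genes were lower. Arntl, which encodes the activator BMAL1 (probe on chromosome 7, 120457261 to 120457320), was 15.0-fold higher in mutants, with a log2 signal of 1.57 ± 0.130 (SD, n = 3) against -2.34 ± 0.411 (SD, n = 3) in controls. Npas2, which encodes a DNA-binding partner of BMAL1 (chromosome 1, 39418941 to 39419000), was at least 5.47-fold higher. Ciart, a repressor of the BMAL1 complex (chromosome 3, 95682433 to 95682492), was at least 12.9-fold lower. Dbp, a clock-controlled transcription factor (chromosome 7, 52965461 to 52965520), fell by 3.59 ± 0.168 (log2, SE). Nr1d2, a nuclear receptor that represses Arntl, fell by 3.03 ± 0.224. The array design places its brightest probe on chromosome 19 (40271435 to 40271494), and whether the gene lies there was not checked. A second Nr1d2 probe was at -2.52. The adjusted p values were 5.81e-06 for Arntl, 8.8e-04 for Npas2, 1.4e-04 for Ciart, 2.1e-06 for Dbp and 9.4e-05 for Nr1d2, and in each of these the 3 mutant values lay outside the range of the 3 control values, which chance gives in 10% of comparisons of 3 with 3. Clock (1.73), Cry1 (1.52) and Nfil3 (1.34) also rose, and Per3, Usp2 and Tef fell, by at least 6.03-fold for Per3 and with log2 differences of -3.45 for Usp2 and -1.53 for Tef. Nr1d1 was at 0.25 (adjusted p = 0.689) and Per2 at -0.79 (adjusted p = 0.0772).

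The probe for mouse Per1 with the brightest signal (chromosome 11, 68923364 to 68923423) fell by 1.67 ± 0.260 in liver at ZT13 (adjusted p = 0.0066), from 2.07 ± 0.200 (SD, n = 3) in controls to 0.40 ± 0.530 (SD, n = 3) in mutants. A dimmer Per1 probe did not follow it, at 0.52 (adjusted p = 0.589). The labels do not say whether either probe also binds the human PER1 transcript, so the source of the signal is open wherever Per1 is given.

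Outside the clock, other genes passed in liver at ZT13. Lpin1, a phosphatidate phosphatase of triglyceride synthesis, fell 15.0-fold (log2 -3.90 ± 0.222). Mfsd2a, a lysophospholipid transporter, was at -3.69, Ppp1r3g, a subunit that brings a phosphatase to glycogen, at -4.82, Rgs16, a regulator of G protein signalling, at -3.83, and Pcsk4, a proprotein convertase, at -3.53. Aipl1 was at least 7.07-fold lower. Higher in mutants were Elovl3, an elongase of very long chain fatty acids (8.03-fold), Loxl4, a lysyl oxidase (11.9-fold), Dhrs9, a short-chain dehydrogenase (at least 4.09-fold), and Acnat2, Lgalsl, Srgap3, Srms and Spon2, with log2 differences of 2.87 to 2.94. In all, 723 of 25469 genes passed (355 higher, 368 lower). Within slide 3 alone, 966 genes passed and the values stayed close, at 4.14 for Arntl, -3.70 for Dbp and -4.11 for Lpin1, while Nfil3 (adjusted p = 0.0598) and Srgap3 (adjusted p = 0.0522) no longer passed. The count was 347 without control replicate 2, 275 without control replicate 3, and 313, 316 and 279 without mutant replicates 1, 2 and 3.

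By gene list, 6 of the 8 daytime clock genes fell and none rose in liver at ZT13 (7 fell adjusted over the list alone), with a median of -3.24 and an adjusted p of 2.1e-16, or 0.0032 with an estimated correlation. All 5 late-night genes rose, over all genes and adjusted over the list alone, with a median of 1.73 (adjusted p = 5.2e-13, or 0.0019 with an estimated correlation). Of the 23 core clock genes 5 rose and 7 fell (5 and 11 adjusted over the list alone; adjusted p = 0.0019, or 0.0451 with an estimated correlation). Among genes of gluconeogenesis and glucose use, 6 of 20 fell (7 adjusted over the list alone), including Pfkfb3, a regulator of glycolytic flux (-2.01), the serine dehydratase gene Sds (-1.73), liver glycogen synthase Gys2 (-1.07) and the transcription factor Foxo1 (-0.92). The shift of that list had an adjusted p of 5.4e-05, and an adjusted p of 0.134 with an estimated correlation. Glucocorticoid responsive genes fell in 4 of 17 cases (5 adjusted over the list alone), with Zbtb16 at -2.09 and Fkbp5, a cochaperone of the glucocorticoid receptor, at -1.14. Among the 4 was the core clock gene Per1, whose brightest probe was at -1.67 and a dimmer probe at 0.52. The shift of the glucocorticoid list had an adjusted p of 4.1e-05, and an adjusted p of 0.144 with an estimated correlation. In cholesterol synthesis Mvd (1.94) and Hmgcs1 (0.59), enzymes of the mevalonate pathway, rose and no gene fell (3 and 1 adjusted over the list alone; adjusted p = 0.0067, or 0.533 with an estimated correlation). In the unfolded protein and amino acid response the endoplasmic reticulum genes Sdf2l1 (1.72) and Creld2 (1.39) rose while Chac1 (-2.37) and Trib3 (-1.18), targets of the amino acid response, fell, 3 up and 2 down in all (6 and 2 adjusted over the list alone; adjusted p = 0.0066, or 0.0628 with an estimated correlation). Markers of mesothelium shifted up with no member past the threshold, over all genes or adjusted over the list alone (median 0.71, adjusted p = 0.014, or 0.515 with an estimated correlation).

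The other lists did not pass in liver at ZT13, though single members of several did. Pdk4, a kinase that blocks pyruvate oxidation, rose by 2.41 and the carnitine transferase gene Cpt1a fell by 0.81 among PPAR alpha targets (adjusted p of the list 0.206). Alas1, the rate-limiting enzyme of haem synthesis (-1.11), and the reductase gene Por (-1.40) fell in the list of PAR bZIP and xenobiotic metabolism (0.101). Dusp1 fell among immediate early genes (0.237), Pnpla2 among lipolysis genes (0.0786), and Nampt and Cebpd among adipokines and adipogenic regulators (0.206), while Hspb1 and Chordc1 rose among heat shock genes (0.123). The adjusted p was 0.226 for fatty acid and triglyceride synthesis, 0.862 for bile acid genes, 0.0667 for ribosome biogenesis, 0.226 for oxidative phosphorylation, 0.156 for male-biased and 0.552 for female-biased liver genes, 0.49 for acute phase, 0.485 for interferon responsive and 0.52 for proliferation genes. For markers of other cell types it was 0.0667 for neutrophils, 0.115 for fibroblasts and stellate cells, 0.237 for erythroid cells and for brown adipocytes, 0.342 for skeletal muscle, 0.71 for T cells, 0.714 for endothelium, 0.809 for macrophages, 0.816 for adipocytes and for B cells, 0.941 for hepatocytes and 0.944 for pancreas acinar cells.

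**Figure D2:**
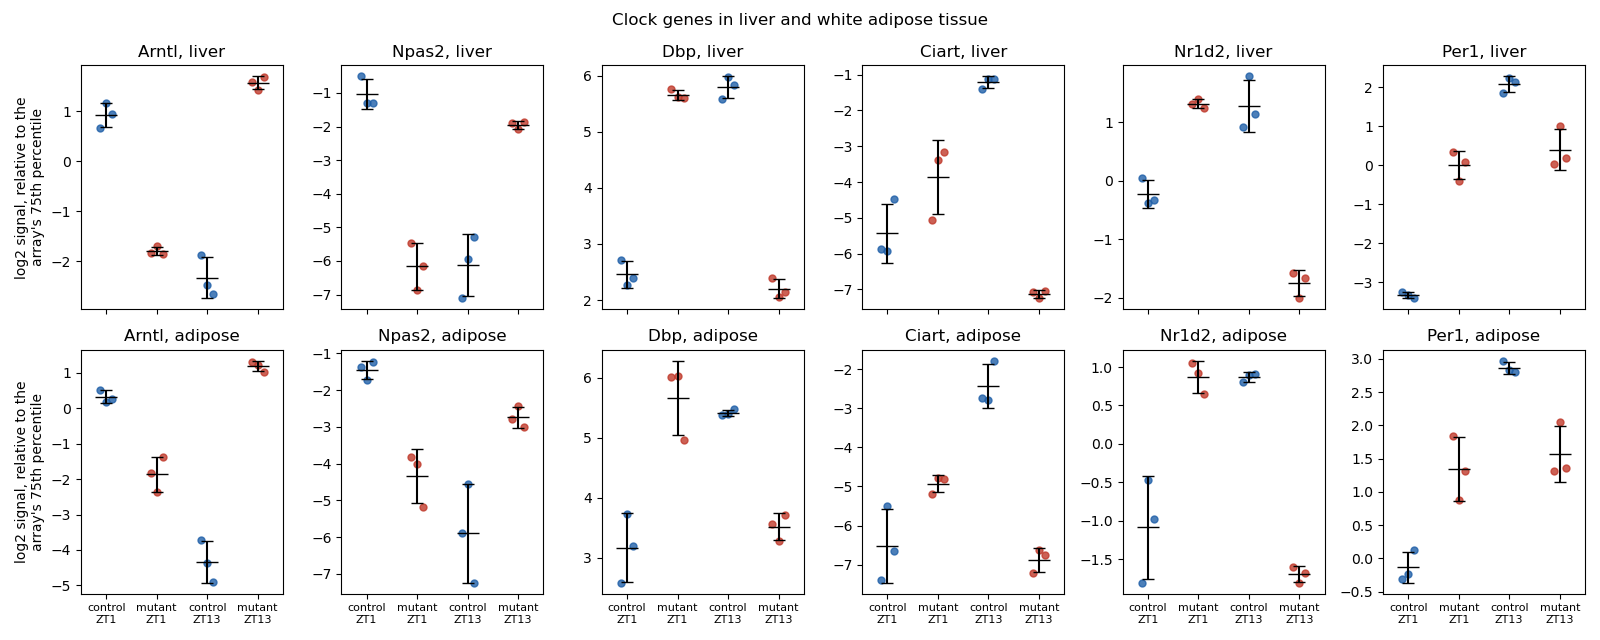
Log2 signal of Arntl, Npas2, Dbp, Ciart, Nr1d2 and Per1 relative to the array's 75th percentile, in liver (top) and adipose tissue (bottom), for control (blue) and mutant (red) mice at ZT1 and ZT13. Points are single arrays and black bars the mean ± SD (n = 3); for Arntl in liver, controls go from 0.93 at ZT1 to -2.34 at ZT13 and mutants from -1.80 to 1.57.

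At ZT1 in liver the clock genes differed in the opposite direction. Dbp was 9.21-fold higher in mutants (log2 3.20 ± 0.168, SE, adjusted p = 4.2e-06), Per2 rose by 2.70, Usp2 by 3.38 and Tef by 1.98. Bhlhe40, a clock-controlled repressor, rose by 3.50, and the brightest Per1 probe by 3.34 ± 0.260, while the dimmer Per1 probe was at -0.49 (adjusted p = 0.286). Npas2 was at least 8.61-fold lower, Cry1 was at least 1.33-fold lower, and Arntl (-2.73), Nfil3 (-2.46) and Clock (-0.77) fell. Among lipid genes Fasn, the fatty acid synthase, rose by 3.23, Lpin1 by 2.28, Me1 by 1.38 and Acly by 1.17. The Myc family member Mycl was at least 10.9-fold higher, Coq10b and Gnat1 rose by 3.25 and 3.58, and Loxl4 fell by 3.47.

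In this comparison 11471 of 25469 genes passed (4456 higher, 7015 lower), and the median difference of all genes was -0.17. All 3 control arrays were on slide 1 and all 3 mutant arrays on slide 2. Every difference here is thus one between slides too. A fit over all 24 arrays gave 8341 genes and a median SE of 0.292, and with slide as a fixed block in it 88 genes and 0.460. The step from slide 1 to slide 2 in that block came only from adipose mutant ZT1, replicate 3 against replicates 1 and 2. The step from slide 2 to slide 3 came only from liver control ZT13, replicate 1 against replicates 2 and 3. Each step was taken as equal in both tissues, so all values with the block rest on these few arrays. Of the 88, 60 were among the 11471, and Dbp (4.27), Usp2 (3.71), Arntl (-3.45), Per1 (3.38), Tef (1.97), Lpin1 (2.01), Loxl4 (-3.50), Gnat1 (4.15) and Cry1 still passed. Other genes above did not pass with that block, with smaller differences and larger SE in most. Fasn went from 3.23 ± 0.516 (SE) to 0.95 ± 0.587 (adjusted p = 0.686), Bhlhe40 from 3.50 ± 0.534 to 1.69 ± 0.870 (0.578), Coq10b from 3.25 ± 0.411 to 1.25 ± 0.509 (0.437), Per2 from 2.70 ± 0.277 to 1.88 ± 0.444 (0.0931) and Nfil3 from -2.46 ± 0.353 to -1.54 ± 0.609 (0.421). Me1 went from 1.38 ± 0.267 to 0.67 ± 0.454 (0.716), Acly from 1.17 ± 0.420 to -0.14 ± 0.688 (0.975) and Clock from -0.77 ± 0.195 to -1.29 ± 0.320 (0.116). Npas2 and Mycl, for which bounds are given, had an adjusted p of 0.0646 and 0.952.

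Among lists in liver at ZT1, 7 of 8 daytime clock genes rose and none fell (7 adjusted over the list alone; median 1.78, adjusted p = 2.6e-05, and an adjusted p of 0.0986 with an estimated correlation). All 5 late-night genes fell (5 adjusted over the list alone; median -2.46, adjusted p = 0.0015, and 0.0986 with an estimated correlation). In fatty acid and triglyceride synthesis 7 of 22 rose and none fell (7 adjusted over the list alone; median 0.31, adjusted p = 0.008, and an adjusted p of 0.495 with an estimated correlation). That list's adjusted p was 0.162 with the slide block, whereas both clock arms still passed with medians of 1.64 and -3.45. Cholesterol synthesis, where 9 of 22 genes rose (8 adjusted over the list alone), had an adjusted p of 0.0589, and hepatocyte markers, among them Alb (-0.88) and Ahsg (-0.94), had 3 of 12 lower (2 adjusted over the list alone) with an adjusted p of 0.824. Averaged over both times, 5748 genes passed in liver (2558 higher, 3190 lower). The count was 9266 without control ZT1 replicate 2, 3554 without mutant ZT1 replicate 2, 3103 without mutant ZT13 replicate 2, 1486 in a fit over 24 arrays and 73 with slide as a fixed block in that fit. The cholesterol synthesis genes Mvd (1.35) and Lss (0.98) rose, and the list's 8 higher and 0 lower members (equal adjusted over the list alone) gave an adjusted p of 0.0029, and of 0.918 with an estimated correlation.

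In adipose tissue at ZT13 the same clock genes led the difference. Arntl was 46.1-fold higher in mutants, at 1.19 ± 0.152 (SD, n = 3) against -4.33 ± 0.592 (SD, n = 3) in controls (adjusted p = 4.8e-05). Ciart was at least 7.75-fold lower (adjusted p = 0.0039), and Nr1d2 fell by 2.57 ± 0.295 (SE, adjusted p = 0.0096). Pcsk4 (-2.37) and the mitochondrial folate enzyme gene Mthfd1l (-1.87) fell. Asb12 rose by 3.42 and Xrcc3, a gene of recombination repair, by 1.97. Not past the threshold were Npas2 (3.16, adjusted p = 0.137), Dbp (-1.90, adjusted p = 0.137), Clock (1.40, adjusted p = 0.111) and Per1 (-1.30, adjusted p = 0.317). A second, dimmer Dbp probe passed in a fit of all probes (-2.89, adjusted p = 0.0296). A second Nr1d2 probe had the same sign there and did not pass (-2.80, adjusted p = 0.195).

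Of 27895 genes, 11 passed in adipose tissue at ZT13 (4 higher, 7 lower). Among genes tested in both tissues 6 passed here, and 5 of them (Arntl, Ciart, Mthfd1l, Nr1d2 and Pcsk4) also passed in liver in the same direction. Xrcc3 was at 0.43 in liver (adjusted p = 0.402) and was not among the genes whose genotype effect differed between tissues at ZT13. For Npas2, Dbp, Clock and Per1 that difference had an adjusted p of 1, 0.104, 1 and 1. The count was 5 without control replicate 3, 3 without mutant replicate 1, and 5 without mutant replicate 2 or 3. All control arrays were on slide 2 and all mutant arrays on slide 3. A fit over 24 arrays gave 48 genes and a median SE of 0.308, and with slide as a fixed block in it 22 and 0.487. With that block Arntl (6.22), Nr1d2 (-3.11), Pcsk4 (-2.64) and Xrcc3 (2.25) still passed. Ciart (adjusted p = 0.0817) and Mthfd1l (-1.87 ± 0.255, SE, without the block and -2.09 ± 0.456 with it, adjusted p = 0.202) did not. Asb12 did not pass over 24 arrays without the block either (adjusted p = 0.214). Dbp passed without the block (adjusted p = 0.00286) and with it (-2.21, adjusted p = 0.0416).

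The daytime arm had 2 of 8 members lower at ZT13 in adipose tissue (8 adjusted over the list alone), with a median of -1.75 (adjusted p = 1.5e-24, or 0.0024 with an estimated correlation). The late-night arm had 1 of 5 higher (4 adjusted over the list alone), with a median of 1.46 (adjusted p = 1e-13, or 0.0016 with an estimated correlation), and the core clock had 1 higher and 2 lower (4 and 11 adjusted over the list alone; adjusted p = 3.2e-05, or 0.0231 with an estimated correlation). Macrophage markers shifted down (median -0.50, adjusted p = 3.5e-07) with no member past the threshold over all genes and 4 of 16 lower adjusted over the list alone, and an adjusted p of 0.113 with an estimated correlation. Ribosome biogenesis (0.24), interferon responsive genes (0.48) and endothelial markers (0.40) had positive medians, with adjusted p of 0.0034, 0.005 and 0.005, and of 0.138, 0.485 and 0.217 with an estimated correlation. Hepatocyte markers had a median of -1.46 in the same arrays (adjusted p = 0.0082, or 0.519 with an estimated correlation). Lists rich in liver transcripts moved with them, namely bile acid genes (-1.26, adjusted p = 0.0025, or 0.485 with an estimated correlation), PAR bZIP and xenobiotic metabolism (-0.62, adjusted p = 0.0013, or 0.485) and gluconeogenesis (-0.37, adjusted p = 0.0036, or 0.459).

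In adipose tissue at ZT1 no gene passed in limma, and 2053 of 27895 had an unadjusted p under 0.05. The count was 16 without mutant replicate 1, 6 without mutant replicate 3, and 1 without control replicate 1 or mutant replicate 2. The genes of lowest p were largely clock genes with the signs seen in liver at ZT1, all at an adjusted p of 0.119. Dbp was at 2.50 ± 0.341 (SE), Per2 at 2.04, Nr1d2 at 1.96, Tef at 1.61 and Arntl at -2.19, beside Pcdh20 (2.40) and the chemokine gene Cxcl13 (-1.91). The daytime arm was higher as a list, with no member past the threshold over all genes and 7 of 8 higher adjusted over the list alone (median 1.61, adjusted p = 5.7e-16, or 0.0104 with an estimated correlation). The late-night arm was lower, with 5 of 5 members adjusted over the list alone (median -2.19, adjusted p = 7.9e-10, or 0.0052 with an estimated correlation). Within slide 1 both arms kept their direction, at 1.57 and -2.43, with Dbp at 2.86 and Arntl at -2.43 (adjusted p = 0.88 for both genes), and a fit over 24 arrays gave 50 genes without and 160 with slide as a fixed block, the latter with Dbp, Arntl, Cry1, Nr1d2 and Per1.

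Hepatocyte markers were also lower in mutant adipose tissue at ZT1, with a median of -3.52 (adjusted p = 5.2e-08, or 0.397 with an estimated correlation) and no member past the threshold over all genes tested. Male-biased liver genes (-2.51, 1 higher and 5 lower adjusted over the list alone, adjusted p = 2.5e-08, or 0.355 with an estimated correlation), bile acid genes (-1.92, adjusted p = 1.6e-05, or 0.439) and xenobiotic metabolism (-1.54, adjusted p = 0.018, or 0.576) moved with them. Cholesterol synthesis genes had a median of -0.38 (adjusted p = 0.0012, or 0.511 with an estimated correlation) and interferon responsive genes of -0.37 (adjusted p = 0.0015, or 0.501). Macrophage and brown adipocyte markers also passed at the preset correlation, with no member past the threshold over all genes. Among macrophage markers of lowest p, Itgax (0.68), Lyz2 (0.55) and Trem2 (0.76) were higher in mutants and Clec4f (-1.95) lower. Among brown adipocyte markers Otop1 (-1.17), Cidea (-1.47) and Cox8b (-0.61) were lower. Averaged over both times no gene passed in adipose tissue in limma, with 1419 at an unadjusted p under 0.05, and 1 gene passed without mutant ZT1 replicate 3 or mutant ZT13 replicate 2. The lowest adjusted p there was 0.0607, for Pcdh20, and hepatocyte markers had a median of -2.57 (adjusted p = 3.1e-09, or 0.327 with an estimated correlation).

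The clock index, daytime minus late-night genes on a log2 scale, was -1.18 ± 0.277 (SD, n = 3) in control liver at ZT1 and 3.90 ± 0.108 (SD, n = 3) at ZT13. In mutant liver it was 3.28 ± 0.312 at ZT1 and -1.42 ± 0.184 at ZT13. Adipose tissue gave -0.70 ± 0.388 and 3.92 ± 0.464 in controls and 2.81 ± 0.191 and -0.48 ± 0.171 in mutants. Mutant minus control was 4.46 in liver and 3.51 in adipose tissue at ZT1, and -5.32 and -4.40 at ZT13. Each of these had an exact permutation p of 0.1, the smallest that 20 arrangements of 3 against 3 can give. The difference between the times was -9.77 in liver and -7.90 in adipose tissue, each with an exact permutation p of 0.005, the smallest that 400 arrangements can give. Within a slide the difference was -5.26 in liver at ZT13 and 3.62 in adipose tissue at ZT1 (exact permutation p = 0.1 for each, the smallest possible).

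The change from ZT1 to ZT13 in controls gives the daily course against which mutants are set. In control liver Per1 rose by 5.40 ± 0.260 (log2, SE), Usp2 by 5.51, Per2 by 3.97, Bhlhe40 by 3.96 and Dbp by 3.34, and Ciart was at least 5.34-fold higher. Npas2 was at least 10.3-fold lower, and Arntl (-3.26) and Nfil3 (-2.19) fell. Outside the clock, Mfsd2a rose by 5.59, Lpin1 by 4.89, Pfkfb3 by 3.23, Alas1 by 2.93, Gys2 by 2.51, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 2.09, while Pdk4 fell by 3.70 and the immediate early gene Egr1 by 5.24. In all 13053 of 25469 genes passed (5305 higher, 7748 lower; median of all genes -0.17). The daytime arm rose (7 of 8, list median 2.83, adjusted p = 2.4e-05) and 4 of 5 late-night genes fell (-2.19, adjusted p = 0.013), each with an adjusted p of 0.137 with an estimated correlation. Ribosome biogenesis (12 up, 2 down, adjusted p = 0.002), xenobiotic metabolism (8 up, 0 down, adjusted p = 0.0059), heat shock genes with Hspa1a at 2.50 (9 up, 3 down, adjusted p = 0.031), and neutrophil (0 up, 6 down) and T cell markers (0 up, 5 down, each adjusted p = 0.022) also shifted, with adjusted p of 0.469, 0.275, 0.382, 0.382 and 0.382 with an estimated correlation. For these lists the counts were equal adjusted over the list alone. The ZT1 arrays were on slide 1 and the ZT13 arrays on slides 2 and 3, and over 24 arrays 10507 genes passed without and 179 with slide as a fixed block.

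In mutant liver the clock genes changed the other way between the same times. Arntl rose by 3.37 ± 0.207 (SE), Npas2 by at least 4.58-fold and Cry1 by at least 3.73-fold, whereas Dbp (-3.46) and Nr1d2 (-3.07) fell. Bhlha15, a transcription factor of secretory cells, rose by 4.34, and Ppp1r3g (-5.59) and Rgs16 (-4.16) fell. Hspa1a rose in mutants too, by 2.72, as did Dnajb1 (1.25), Creld2 (1.98) and Manf (1.35), the last of the unfolded protein response, while Trib3 fell by 2.34. Of 25469 genes 485 passed (245 higher, 240 lower). The daytime arm had 5 of 8 lower (7 adjusted over the list alone; adjusted p = 6.9e-15, or 0.0044 with an estimated correlation) and all 5 late-night genes rose, also adjusted over the list alone (2.2e-14, or 0.0013). Heat shock genes had 5 higher and 0 lower (6 and 0 adjusted over the list alone; 9.9e-08, or 0.0443), and the unfolded protein response 3 higher and 1 lower (7 and 2 adjusted over the list alone; 9.2e-04, or 0.0346). ZT1 was on slide 2 and ZT13 on slide 3, and over 24 arrays 286 genes passed without and 65 with slide as a fixed block, 39 of the latter being among the 485. Without any single mutant array the count was 80 (ZT13 replicate 3) to 146 (ZT13 replicate 1).

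In control adipose tissue Per2 rose by 4.34 ± 0.324 (SE) from ZT1 to ZT13, Per3 by 4.17 and Per1 by 3.01, and Ciart was at least 4.97-fold higher. Arntl (-4.65) and Npas2 (-4.45) fell, Elovl3 was at least 10.9-fold lower, and the myeloid genes Retnlg (-4.65), Mmp9 (-3.97) and S100a9 (-2.17) fell. Sgk1 (3.51) and Fkbp5 (1.53), both induced by glucocorticoids, rose. Of 27895 genes 3948 passed (1561 higher, 2387 lower; median of all genes -0.28). The daytime arm rose in 7 of 8 genes, also adjusted over the list alone (adjusted p = 4e-10, or 0.0424 with an estimated correlation). Glucocorticoid responsive genes rose in 4 of 17 cases (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.021, and an adjusted p of 0.781 with an estimated correlation). That list also holds the core clock gene Per1. Time and slide coincided, and over 24 arrays 9025 genes passed without and 44 with slide as a fixed block, 21 of the latter being among the 3948. The count was 1604 and 357 without control ZT1 replicates 2 and 3, and 199, 610 and 194 without control ZT13 replicates 1, 2 and 3.

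In mutant adipose tissue Arntl rose by 3.06 ± 0.322 (SE), Nfil3 by 2.47 and Cry1 by at least 2.24-fold, and Nr1d1 (-2.91), Nr1d2 (-2.57) and Dbp (-2.15) fell. The macrophage gene Cd68 (-2.30), the scavenger receptor gene Cd163 (-2.83), Timd4 (-2.87), Mmp12 (-3.48) and Retnlg (-5.11) fell, and the chemokine receptor gene Ccr3 was at least 12.7-fold lower. Of 16 macrophage markers 8 fell (10 adjusted over the list alone; median -1.31, adjusted p = 2.8e-07, and an adjusted p of 0.186 with an estimated correlation). Markers of other cell types shifted down with them. These were fibroblasts and stellate cells (1 of 13 lower, 7 adjusted over the list alone; median -0.61, adjusted p = 0.0025, or 0.432 with an estimated correlation), neutrophils (2 of 7, 3 adjusted over the list alone; -0.86, 0.0069, or 0.234) and T cells (0 of 9, 4 adjusted over the list alone; -1.02, 0.011, or 0.538). Of 27895 genes 428 passed (80 higher, 348 lower; median of all genes -0.14). The count was 10553 without mutant ZT1 replicate 3, the group's array on slide 2, and 100 and 87 without ZT1 replicates 1 and 2. It was 62, 118 and 57 without ZT13 replicates 1, 2 and 3, and over 24 arrays 4002 without and 30 with slide as a fixed block.

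The change with time was itself compared between genotypes. In liver Loxl4 (7.04 ± 0.417, SE) and Arntl (6.64) had positive differences and Ppp1r3g (-7.67), Usp2 (-6.83) and Dbp (-6.80) negative ones. Npas2 was higher and Ciart and Per3 were lower, without a size, since each was not well above background on any array of 2 of the 4 groups, and 7939 of 25469 genes passed (4692 higher, 3247 lower; median of all genes 0.20). All 5 late-night genes were higher, also adjusted over the list alone (adjusted p = 1.8e-06), and 6 of 8 daytime genes lower (8 adjusted over the list alone; 6.1e-10), each with an adjusted p of 0.0164 with an estimated correlation. In adipose tissue Arntl (7.71 ± 0.456), Npas2 (6.05), Nr1d2 (-4.53), Dbp (-4.40), Per1 (-2.78) and Per2 (-3.17) were among the 23 of 27895 genes that passed (10 higher, 13 lower). Their number was 6 without mutant ZT13 replicate 1 or 3, 12 without mutant ZT13 replicate 2 or control ZT13 replicate 1, and 13 without control ZT1 replicate 1 or 3 or control ZT13 replicate 3. The daytime arm had 5 of 8 lower (8 adjusted over the list alone; adjusted p = 2.3e-27, or 0.0017 with an estimated correlation) and the late-night arm 2 of 5 higher (5 adjusted over the list alone; 8.3e-16, or 9.3e-04). Over 24 arrays the liver count was 3925 without and 310 with slide as a fixed block, 265 of the latter being among the 7939. Across genes, which are not independent replicates, the genotype difference at ZT1 and that at ZT13 had a Pearson r of -0.147 in liver and 0.0843 in adipose tissue.

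The genotype effect differed between tissues for 362 of 29143 genes at ZT1 (163 higher in liver, 199 lower) and 41 at ZT13 (22 and 19). The ZT1 count was 8211 without adipose mutant replicate 3 and 63 without liver mutant replicate 3, and leaving out any other array of those groups gave 78 to 870. At ZT1 liver controls were on slide 1 and liver mutants on slide 2. Of the adipose arrays at ZT1 only mutant replicate 3 was off slide 1. At ZT13 adipose controls were on slide 2 and adipose mutants on slide 3, and in liver only control replicate 1 was off slide 3. Slide thus stays open as a source of these tissue differences. Hepatocyte transcripts also varied between adipose arrays, from 0.139% of the liver level (mutant ZT1 replicate 2) to 34.4% (control ZT1 replicate 2). Liver RNA in the adipose samples thus stays open as a source for hepatocyte genes and lists rich in them. The ZT13 count was 18 without adipose mutant replicate 3, and 19 to 51 without the others. At ZT13 the liver effect lay below the adipose one for Lpin1 (-3.69 ± 0.284, SE) and Pfkfb3 (-2.46, with -2.01 in liver and 0.45 in adipose tissue), and above it for Loxl4 (4.04) and Pdk4 (2.94). At ZT1 the liver effect was above the adipose one for Fasn (3.34), Usp2 (2.94) and Per1 (1.86), and below it for Loxl4 (-4.58). At ZT1 fatty acid synthesis (3 of 22 higher, 5 adjusted over the list alone, adjusted p = 4.6e-05, or 0.413 with an estimated correlation) and cholesterol synthesis (1 of 22 higher, 7 adjusted over the list alone, 4.6e-05, or 0.426) shifted, beside hepatocyte markers at 3.25 (1.6e-04, or 0.439). The hepatocyte list was lower in mutant adipose tissue at ZT1, while in liver it did not pass at that time. At ZT13 macrophage markers (0.58, adjusted p = 3e-04) and ribosome biogenesis (-0.39, adjusted p = 3e-04) shifted, each with an adjusted p of 0.266 with an estimated correlation. Lists of hepatocyte, fibroblast and stellate, bile acid, male-biased liver and lipolysis genes also passed at the preset correlation, with no member past the threshold over all genes. Their members of lowest p were, in that order, Cps1 (2.06), Lum (1.03), Slco1a1 (1.55), C6 (-0.98) and Cidec (-1.54).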

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

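The tests of the 3 patterns weighed here were chosen after the results were seen, whereas the differences between times and tissues and the other splits of the samples were planned.

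The genotype effect differed between the times of day, tested as an interaction. In liver 7939 genes passed, with positive values for Npas2 (9.30), Loxl4 (7.04), Arntl (6.64) and Tubb2a-ps2 (4.97). Values were negative for Ppp1r3g (-7.67), Ciart (-7.48), Usp2 (-6.83), Dbp (-6.80) and Per3 (-6.40). In adipose tissue 23 genes passed, with Arntl at 7.71, Npas2 at 6.05, Asb12 at 5.54, Lonrf3 at 3.65, the protease gene Adamts4 at 3.38, Ciart at -6.02, Nr1d2 at -4.53, Dbp at -4.40 and Nr1d1 at -3.22. For Npas2, Ciart and Per3 in liver and Ciart in adipose tissue, at least 2 of the 4 groups had no array well above background, so these values carry a sign and no size. The clock index differed between times by -9.77 in liver and -7.90 in adipose tissue.

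The genotype effect also differed between the tissues, again by a test of the difference itself. Slide parted the genotypes fully in liver at ZT1 and in adipose tissue at ZT13, and only in part in the other tissue. Slide therefore stays open as a source at both times. For hepatocyte transcripts, their varying level between adipose arrays stays open as a source too. At ZT1, 362 genes passed. The effect in liver exceeded that in adipose tissue for Hsbp1l1 (4.76), Tm4sf4 (4.70), the fructose transporter gene Slc2a5 (4.27), Sult1c2 (4.19) and Gnat1 (3.46), and lay below it for Prkg2 (-4.97), Loxl4 (-4.58), Olfr1535 (-4.08), Nrcam (-3.53) and Dclre1b (-3.49). At ZT13, 41 genes passed, with Cldn1 (5.18), Loxl4 (4.04), Smim5 (3.66) and Pdk4 (2.94) on the positive side and Pcdh20 (-4.20), Lpin1 (-3.69), Gpcpd1 (-3.35), Raet1e (-2.75) and Raet1b (-2.63) on the negative side. Hsbp1l1, Tm4sf4, Sult1c2, Gnat1, Prkg2, Olfr1535, Nrcam and Dclre1b at ZT1 and Cldn1, Smim5 and Pcdh20 at ZT13 had at least 1 compared group with no array well above background, so their values are no measure of size.

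Clock genes moved in opposite directions at ZT1 and ZT13. Slide as the whole cause is argued against by the clock index within the slides that hold both genotypes, -5.26 in liver at ZT13 and 3.62 in adipose tissue at ZT1. Exchanged time labels among mutants stay open. The changes with time in controls and in mutants had a Pearson r across genes of 0.641 in adipose tissue and 0.0822 in liver. Genes are not independent replicates, and slide changed with time in both genotypes, so these values do not decide. The index of mutant ZT1 lay near that of control ZT13 (3.28 against 3.90 in liver, 2.81 against 3.92 in adipose tissue), and although 6 of 23 core clock genes in liver and 6 of 23 in adipose tissue differed between those groups, genotype and partly slide differ there too. Mutant ZT13 and control ZT1, on slides 3 and 1, differed for 13 of 23 in liver, such as Per1 (3.73), Per2 (3.18) and Bhlhe40 (3.04), and 7 of 23 in adipose tissue. How many of all genes passed in these crossed comparisons is not given. The counts therefore neither set clock genes apart from other genes nor can be set against each other. An earlier clock phase in mutants stays open as well, since its test (exact permutation p = 0.005 in both tissues, the smallest that 400 arrangements can give) measures the opposite signs themselves, and with 2 times of day a later phase would give the same signs. Exchanged labels and a changed phase cannot be told apart here, and slide stays open for the other genotype comparisons.

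Liver control ZT1 arrays stood apart from the other liver arrays. Scaling of the arrays as the cause is argued against by 10955 genes at ZT1 with quantile normalization. Slide 1 remains a candidate explanation, since the liver difference at ZT1 correlated across genes, which are not independent replicates, with the difference between the slide 2 array and the slide 1 arrays inside the adipose mutant ZT1 group (r = 0.732, rho = 0.758). Setting single arrays against the others of their group gave r from -0.44 to 0.366 in the adipose groups held on 1 slide. Genotype at ZT1 stays open beside it, since 88 genes passed with slide as a fixed block while the median SE rose 1.57 times over the fit of 24 arrays without it.

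Hepatocyte transcripts varied between adipose arrays, from 0.139% of the liver level (mutant ZT1 replicate 2) to 34.4% (control ZT1 replicate 2). Liver RNA in the adipose samples is a candidate explanation, since the mean of 12 hepatocyte markers correlated with that of 14 bile acid genes over 12 arrays (r = 0.867, permutation p = 9.1e-04; rho = 0.874, permutation p = 3.8e-04; r = 0.965 without the 2 farthest arrays). The r lay under the bound of 0.9 set for this test, so the test leaves it open. Genotype is a further candidate explanation, as the markers were lower in mutants by a difference of -2.16 (exact permutation p = 0.025; -2.66 to -1.31 with an array left out). The permutation kept the times, but neither slide nor the code in the titles. Slide parted the genotypes fully in adipose tissue at ZT13. Mutant ZT1 replicates 2 and 3 and control ZT13 replicate 2 differed from the other adipose arrays in title code. Their marker means (-2.29, 2.52 and 1.65) lay below those of the other arrays of their groups. This test thus did not separate genotype from slide or title code. Whether tissue dissection or expression differed between genotypes was not tested.

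Other splits of the same samples show how often another grouping of the arrays gives as many genes. For the average over times in liver, 2 of 100 splits gave as many genes (5748, highest other 6656), for the interaction in liver 1 of 100 (7939, highest other 6656) and for the interaction in adipose tissue 2 of 100 (23, highest other 97), the real split included. As many genes were thus rare among the splits drawn, which does not exclude a random grouping. Exchanging genotypes at ZT13 alone turns the average in liver into the interaction, with 7939 genes, and that split was not drawn for the average. These splits do not hold slide fixed. The highest other split in liver kept the ZT1 arrays parted as they really are for both results, by genotype and by slide alike, so it holds the real difference at ZT1 and does not separate the 2. In adipose tissue it set control ZT1 replicate 3 and mutant ZT1 replicates 1 and 2, all on slide 1, together with the mutant ZT13 arrays of slide 3. Control ZT1 replicates 1 and 2, on the other side, are on slide 1 too. Over 24 arrays the counts were 1486, 3925 and 64 without and 73, 310 and 28 with slide as a fixed block, so slide remains open as a source of the others. For the average in adipose tissue the real count was 0, so that all 100 of 100 splits had to give as many (highest other 27) and the splits say nothing. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real count and the highest other were 11471 and 4 for liver at ZT1, 723 and 1 for liver at ZT13, 13053 and 6 for time in control liver, 485 and 0 for time in mutant liver, 11 and 0 for adipose tissue at ZT13, 3948 and 0 for time in control adipose tissue, 428 and 1 for time in mutant adipose tissue, and 362 and 31, and 41 and 0, for the difference between tissues at ZT1 and ZT13. For adipose tissue at ZT1 the real count was 0 and the highest other 1593, from control replicate 3 with mutant replicates 1 and 2 against the rest, which points to a structure of the samples. Those 3 arrays are all on slide 1, but so are control replicates 1 and 2 on the other side, where only mutant replicate 3 is on slide 2. The split thus does not follow slide alone. Control replicate 2 was also the adipose array with the most hepatocyte transcripts (34.4% of the liver level). What the structure is was not tested. The real comparison over 24 arrays gave 50 genes without and 160 with slide as a fixed block.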

How the results depend on the processing

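Of the alternatives here, leaving out slide 1, leaving out liver-enriched genes and the clock index within a slide were chosen after the data were seen.

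The clock index differences kept their direction under every alternative run, and those between times stayed past the threshold, which a single time with 3 against 3 arrays cannot reach. The ranges were 3.26 to 5.33 (liver ZT1), -5.92 to -3.80 (liver ZT13), -11.3 to -7.07 (liver, between times), 2.54 to 4.01 (adipose ZT1), -5.34 to -3.47 (adipose ZT13) and -9.34 to -6.01 (adipose, between times). Of the tests of named genes under alternatives, 8038 kept direction and side, 626 no longer passed, 158 passed newly and 1 reversed. Of those of gene lists that had passed, 2213 kept both, 337 no longer passed and 12 reversed. Of 490 pairs of list and contrast, 127 passed with the preset correlation and 20 with an estimated correlation.

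With slide as a fixed block in the fit over all 24 arrays the counts were in liver 88 (ZT1), 73 (average), 179 (time, control), 65 (time, mutant) and 310 (interaction), in adipose tissue 160 (ZT1), 22 (ZT13), 9 (average), 44 (time, control) and 30 (time, mutant), and 75 for the tissue difference at ZT1. In liver at ZT1 the median SE was 0.292 in that fit without the block and 0.460 with it, and the count without it was 8341. With slide as a random block they were 2109 for time in mutant liver, 9 and 1 for time in control and mutant adipose tissue, 1 for adipose ZT13 and for the adipose interaction, and 65 and 21 for the tissue difference at ZT1 and ZT13. Why the blocks moved the other counts was not tested.

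Without slide 1 arrays, fewer arrays entered and the counts were 1909 (liver ZT13), 1447 (liver time, mutant), 20 (adipose ZT13) and 64 (adipose time, mutant). With only the 6 arrays compared they were 1159 (liver ZT13), 1292 (liver time, mutant), 6833 and 10 (adipose time, control and mutant) and 20 (adipose ZT13). In 1 fit over all 24 arrays they were 9025 and 4002 (adipose time, control and mutant), 50, 48, 13 and 64 (adipose ZT1, ZT13, average and interaction), and 286, 1486 and 3925 (liver time in mutants, average and interaction). A replicate block, although correlations of numbered replicates of -0.52 to 0.15 gave no pairing, gave 928 and 123 (adipose time, control and mutant), 5 (adipose ZT13), 11 (adipose interaction), 297 (liver time, mutant) and 241 (tissue difference at ZT1, mouse as a random block). The title code as a covariate gave 527 and 70 (adipose time, control and mutant) and 3 (adipose interaction). The cause was not tested.

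With no filter on dim probes the counts were 675 and 12 (adipose time in mutants and interaction), 65 and 19 (tissue difference at ZT1 and ZT13), and 47, 206, 1983 and 4292 (liver time in mutants, ZT13, average and interaction), with more genes tested. The strict filter gave 6 (adipose ZT13). Quantile normalization gave 1 (adipose average) and 24 (tissue difference at ZT13). Normexp gave 7209 (adipose time, control), 4 (adipose ZT1), 36 (adipose interaction) and 838 (tissue difference at ZT1). A trend in the prior gave 35 (adipose interaction). Without the 910 genes over 8-fold higher in liver, 1 gene passed for the adipose average. The cause was not tested.

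Scaling also moved the balance of directions. Quantile normalization gave 63.7% higher against 39.5% (adipose time, control), 37.0% against 18.7% (adipose time, mutant), 23.1% against 36.4% (adipose ZT13), 61.7% against 45.0% (tissue difference at ZT1) and 56.5% against 44.5% (liver average), and normexp 25.5% against 39.5% (adipose time, control).

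With slide as a fixed block Csnk1e in control liver over time reversed to 0.15, as did the lists of PAR bZIP and xenobiotic metabolism (0.0039) and PPAR alpha targets (0.020) there, cholesterol synthesis in liver averaged over times (-0.0093) and proliferation in the adipose interaction (0.11). Hepatocyte markers in the adipose interaction reversed with the title code (-0.65) and without mutant ZT1 replicate 2, where the direction of the test changed at a median of 0.11, the lowest of 0.11 to 3.25 with a replicate left out. PAR bZIP and xenobiotic metabolism in adipose tissue reversed with the strict filter at ZT1 (0.21) and on average (0.040). Without genes over 8-fold higher in liver it reversed at ZT1 (0.17), as did acute phase at ZT1 (0.21) and on average (0.23) and gluconeogenesis at ZT1, by its test and not its median (-0.16). The last alternative left out members of these lists, and the cause of the others was not tested.

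With a replicate left out, fewer arrays entered. Counts ran from 275 to 644 (liver ZT13), 3103 to 9266 (liver average), 80 to 146 (liver time, mutant), 0 to 16 (adipose ZT1), 3 to 13 (adipose ZT13), 0 to 1 (adipose average), 194 to 2987 (adipose time, control), 57 to 10553 (adipose time, mutant), 6 to 29 (adipose interaction), 63 to 8211 (tissue difference at ZT1) and 18 to 51 (tissue difference at ZT13). The arrays behind the ends beyond 1.5 times are liver control ZT13 replicate 3 (275), liver mutant ZT13 replicate 2 (3103), liver control ZT1 replicate 2 (9266), liver mutant ZT13 replicate 3 (80), adipose mutant ZT1 replicate 1 (16), adipose mutant ZT13 replicate 1 (3 for ZT13, 6 for the interaction), adipose control ZT13 replicate 3 (194), adipose mutant ZT13 replicate 3 (57 and 18) and ZT1 replicate 3 (10553 and 8211), and liver mutant ZT1 replicate 3 (63). Arrays with signal well above background on 45.5% to 71.2% of spots limit what can be said of dim genes, for which bounds on the fold are given.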

Other observations

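Crossed comparisons of times were added after the results were seen, as were their tests. Mutant ZT13 set against control ZT1 differed for 13 of 23 core clock genes in liver, among them Per1 (3.73), Per2 (3.18), Bhlhe40 (3.04), Usp2 (2.06) and Nr1d2 (-1.53). In adipose tissue 7 of 23 differed, namely Per2 (3.21), Bhlhe40 (3.13), Per3 (2.02), Per1 (1.71), Usp2 (1.46), Tef (1.38) and Nr1d1 (-1.29). The share of all genes that passed in these crossed comparisons is not given. The liver control ZT1 arrays differed widely in general, with 11471 of 25469 genes past the threshold against mutant ZT1. The counts of clock genes therefore do not set them apart from other genes. A second probe was followed for some clock genes. For Dbp it gave 4.60 at ZT1 and -4.60 at ZT13 in liver. For Nr1d2 it gave 4.27 and -2.52 there, where the brightest probe gave 1.54 and -3.03. In adipose tissue the second Per1 probe gave 1.08 and -0.60, neither past the threshold.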
